A study of Mus musculus with 10 samples.

How the data were processed

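Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on nephron progenitors of the mouse embryonic kidney, the Six2-expressing mesenchymal cells that give rise to the epithelium of the nephron. Per the labels' protocols, the progenitors were sorted by FACS at embryonic day 16.5 from kidneys carrying a BAC transgene, Six2GFPcre. Six2 was mapped in freshly sorted cells. β-catenin was mapped in sorted cells that had been pelleted and then cultured for 24 h with 4 µM BIO, an inhibitor of the kinase GSK3 that stabilises β-catenin. Per the labels' protocols, fragments of 250 to 500 bp were gel-purified and amplified with 18 PCR cycles. The series holds 10 samples. They are 2 Six2 libraries, 2 β-catenin libraries, 4 input DNA libraries and 2 rabbit IgG mock libraries. The labels give the BIO culture for some of the input libraries and for neither mock library. Only the peak lists of the 4 libraries with a specific antibody were analysed here. The 6 input and mock samples entered no comparison.

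The deposited values are of a kind other than counts or signal: each file lists the start and end coordinates of peaks, with 3 columns (chromosome, start, end) and no header, score, p-value or read count. The sequencing depth behind each peak is therefore unknown. The submitters' processing notes name the mm9 mouse build and CASAVA version 1.6. The peak caller, its threshold and the control used for each call are not given in the sources used here. Each list belongs to 1 library, so the lists of the 2 libraries of an antibody can be compared. Coordinates were read as BED intervals, and positions are given 1-based. The number of peaks in a list depends on depth and threshold as well as on binding, so list lengths were not compared as amounts of binding.

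The rows are not sorted by position. Whether their order behaves as a rank was tested with the share of peaks found in the other library of the same antibody. A two-sided permutation test of the mean row number of found and not found peaks used 100000 permutations. Row number is called rank below, with rank 1 for the first row. Mean ranks are means of row numbers, so that the longer list of a pair weighs more in them.

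Peaks of 2 lists were counted as overlapping when they shared at least 1 bp. Peaks of the 2 libraries of an antibody were merged, and merged regions with a peak from both libraries are called reproducible regions. Overlap was compared with 1000 random placements of the counted list, in which each peak kept its chromosome and width. Placements ran between the outermost peaks of all 4 lists on that chromosome, since chromosome lengths of mm9 were not used here. This permutation of positions was tested one-sided, and the smallest p it can give is 0.001. It compares the lists at hand, does not allow for mappability or open chromatin, and is no test across replicates. With 2 libraries per antibody, the 4 libraries split into pairs in 3 ways, so that no exact permutation test across libraries can go below p = 0.333. The labels do not say whether libraries of one antibody came from separate sorts or cultures, and replicates were numbered in accession order, which pairs no samples. Shares are given with 95% exact (Clopper-Pearson) intervals, which treat peaks as independent and cover counting error only. Shares of regions were compared with two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg within a family.

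The test of overlap was run on simulated lists before use. For the Six2 pair (1622 peaks moved), 20 lists with no shared sites gave 0 with p below 0.05, and lists with 5% or 40% shared sites gave back 4.97% and 40.0% on average. For the β-catenin pair (1208 peaks moved), 0 of 20 unrelated lists passed, and 4.96% and 40.0% were recovered. Unrelated peaks were placed as in the test itself, and shared ones were centred on partner midpoints. The simulation therefore checked the calculation and did not cover peaks that cluster along chromosomes.

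Alternatives fixed before the data were examined were a reciprocal overlap of 50%, midpoints within 500 bp, the first 50% of each list, moves of 10 to 50 kb in place of whole-chromosome placement, and leaving out each library. Lists without chromosome X, without the chromosome 2 block described below, the widest 50% of each list, any Six2 peak as partner, ranks divided by list length, the recovery of β-catenin replicate 2 peaks at like rank and the comparisons of lists cut to equal length were added after seeing the data. The regions named are the 10 reproducible regions of each antibody and the 10 shared regions with the lowest mean rank, a rule fixed beforehand. Regions named outside that rule are said to be so. The gene table used here is of assembly GRCm38, and positions were not converted between builds. The planned annotation of peaks to genes, the planned tests of gene lists and the planned motif counts were therefore not run, and regions are named by position alone. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.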

Results

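Binding sites of 2 regulators were mapped in sorted nephron progenitors of the mouse kidney. Six2 is a homeodomain transcription factor that keeps these cells in the progenitor state. β-catenin is the transcriptional co-activator of canonical Wnt signalling, the signal that commits progenitors to form epithelium, and it reaches DNA through TCF/LEF factors. Six2 was immunoprecipitated from fresh cells and β-catenin from cells treated for 24 h with 4 µM BIO. The antibody and the state of the cells therefore changed together, and the maps do not separate them. Six2 replicate 1 had 5645 peaks with a median width of 146 bp, and replicate 2 had 1622 peaks with a median width of 207 bp. β-catenin replicate 1 had 1873 peaks (median 140 bp) and replicate 2 had 1208 (median 131 bp). The peaks covered 947.5 kb and 363.4 kb in the Six2 libraries, and 336.6 kb and 179.5 kb in the β-catenin libraries.

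The first peaks of every list were the ones most often found in the other library of the same antibody. In Six2 replicate 1 the share found in replicate 2 fell from 76.5% in the first decile of the list to 4.79% in the last decile. In Six2 replicate 2 it fell from 98.2% to 74.7%. For β-catenin the share fell from 85.1% to 4.81% in replicate 1 and from 90.9% to 20.8% in replicate 2. Peaks that were found again had lower row numbers than the others in all 4 lists (two-sided permutation test, p = 1e-05 in each, the smallest that 100000 permutations can give). Row number was therefore used as the rank of a peak.

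**Figure D1:**
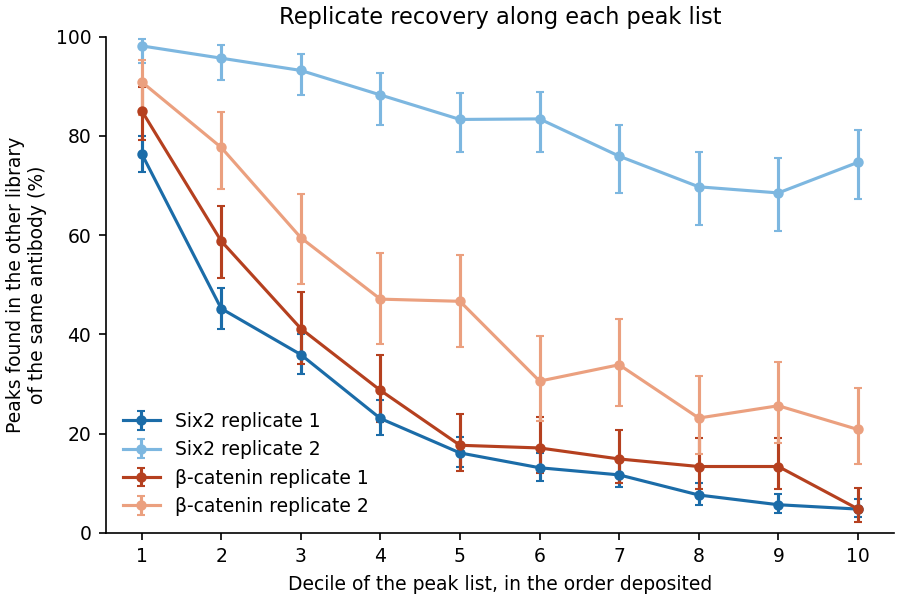
Share of peaks (%) that overlap a peak of the other library of the same antibody, by decile of each list in its deposited order, with 95% exact intervals. All 4 lines start at 76.5% or more in the first decile and end lower, at 4.79% for Six2 replicate 1 and 74.7% for Six2 replicate 2.

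The Six2 peaks included a set of sites that both libraries found. Without the input and mock libraries, Six2 binding was not separated from places that give signal in any ChIP library. Of the 1622 peaks of Six2 replicate 2, 1348 overlapped a peak of replicate 1, which is 83.1% (95% exact interval 81.2 to 84.9%), and 1.52 were reached on average by random placement (highest of 1000 placements 8, permutation p = 0.001). In the longer list of replicate 1, 1353 of 5645 peaks (24.0%, 22.9 to 25.1%) overlapped one of replicate 2. Merging gave 1348 reproducible Six2 regions with a median width of 243 bp. Across these regions the ranks in the libraries were correlated (Spearman's rho = 0.48, permutation p = 1e-05), though regions are not independent replicates.

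The leading Six2 regions lay on several chromosomes. A region at chromosome 16, 6686365 to 6686664 (mm9), ranked 1 in replicate 1 and 2 in replicate 2, and one at chromosome X, 166412626 to 166413210, ranked 2 and 1. A region at chromosome 11, 96270032 to 96270285, ranked 3 in both libraries. The other regions of the first 10 were at chromosome 14, 29586336 to 29586505, chromosome 16, 30034305 to 30034944, chromosome 1, 16284023 to 16284223, chromosome 1, 129297415 to 129297609, chromosome 18, 57067075 to 57067261, chromosome 14, 77312219 to 77312503, and chromosome 10, 42723027 to 42723283. Of these 10 regions, 5 were overlapped by peaks of both β-catenin libraries, at ranks from 43 to 1067, and the other 5 by neither. Among the first 10 peaks of replicate 1, 8 were found in replicate 2. The 2 that were not, chosen after their values were seen, were wide peaks of 894 and 1930 bp next to each other at chromosome 1, 24620692 to 24621585 and 24618520 to 24620449. All of the first 10 peaks of replicate 2 were found in replicate 1.

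The β-catenin peaks of BIO-treated progenitors also included sites that both libraries found. Places that give signal in any ChIP library were not separated from binding here either. Of the 1208 peaks of β-catenin replicate 2, 551 overlapped replicate 1, which is 45.6% (42.8 to 48.5%), against 0.317 by random placement (highest 3, permutation p = 0.001). Of the 1873 peaks of replicate 1, 553 (29.5%, 27.5 to 31.7%) overlapped replicate 2. Merging gave 551 reproducible β-catenin regions with a median width of 188 bp, and their ranks in the libraries were correlated (rho = 0.52, permutation p = 1e-05 across regions). The first 10 peaks of each β-catenin library were all found in the other. A block of 146 peaks of replicate 1 on chromosome 2, from 146903063 to 147136350, held 7.79% of that list, and replicate 2 had 0 peaks there. None of its peaks was in the reproducible set, so the count of 551 was the same without it.

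The β-catenin regions at chromosome 4, 136773190 to 136773332, and at chromosome 11, 80908557 to 80908734, had the lowest mean rank, 2.0 each. The chromosome 4 region was rank 1 in replicate 1 and rank 3 in replicate 2, and Six2 peaks overlapped it in both Six2 libraries, at ranks 192 and 259. The chromosome 11 region was rank 3 and rank 1 and overlapped no Six2 peak. A region at chromosome 17, 86147430 to 86147586, was rank 2 and 7. It overlapped a Six2 peak of replicate 1 alone, of rank 2261. A reproducible Six2 region of ranks 87 and 9, named here after its values were seen, began 393 bp further along, at 86147980 to 86148273. β-catenin replicate 2 had a peak of rank 340 on that neighbour and replicate 1 had none. The remaining leading β-catenin regions were at chromosome 11, 120572249 to 120572387, chromosome 3, 67513329 to 67513517, chromosome 14, 22810535 to 22810726, chromosome 8, 27943927 to 27944102, chromosome 2, 172667988 to 172668137, chromosome 13, 94853209 to 94853346, and chromosome 1, 92194363 to 92194536. Of the first 10 β-catenin regions, 7 overlapped a Six2 peak of at least 1 library and 5 of both, at Six2 ranks from 91 to 5554.

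**Figure D2:**
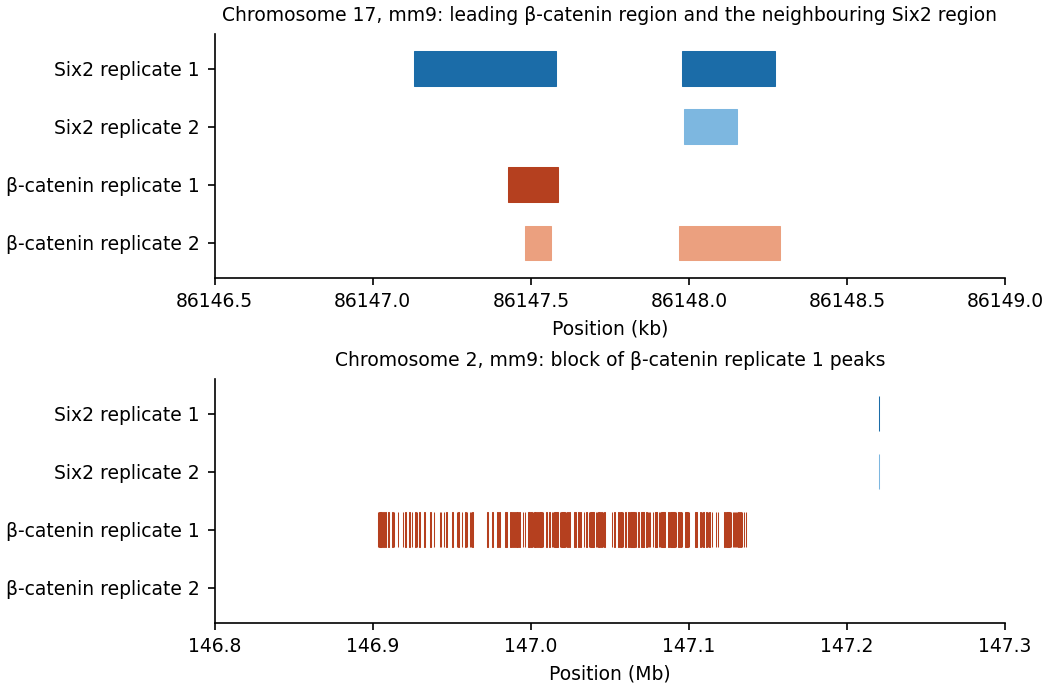
Peaks of the 4 libraries drawn to scale in mm9, 1 row per library, with position in kb on chromosome 17 (top) and in Mb on chromosome 2 (bottom). On chromosome 17 the leading β-catenin region and the Six2 region 393 bp away are separate boxes; on chromosome 2 the 146 peaks of the block are in β-catenin replicate 1 alone.

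The comparison of the maps asks how far the peaks of Six2 and β-catenin fall on the same sites in these progenitors. Of the 551 reproducible β-catenin regions, 123 overlapped a reproducible Six2 region, which is 22.3% (18.9 to 26.0%). Random placement gave 0.134 such regions on average and 2 at most (permutation p = 0.001). Seen from the other side, 123 of the 1348 reproducible Six2 regions (9.13%, 7.64 to 10.8%) lay on a reproducible β-catenin region. Counting any Six2 peak, 260 β-catenin regions (47.2%, 43.0 to 51.5%) were on Six2 sites and 291 (52.8%) were not. Counting any β-catenin peak, 358 Six2 regions (26.6%, 24.2 to 29.0%) were on β-catenin sites and 990 (73.4%) were not. The share depended on the library used. It was 45.4% (250 regions) without Six2 replicate 2 and 12.4% (150 peaks) without β-catenin replicate 1. Without β-catenin replicate 2 it was 17.8%, of a longer list, so that 334 peaks were shared. A reciprocal overlap of 50%, asked of the libraries of an antibody as well, left 29 shared regions of 318 reproducible β-catenin regions (9.12%), again above placement (permutation p = 0.001).

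By mean row number over the 4 libraries, not scaled for list length, the shared regions were led by the site at chromosome 11, 96270032 to 96270285, with Six2 ranks of 3 and 3 and β-catenin ranks of 97 and 63. It was followed by chromosome 14, 77312219 to 77312503 (Six2 ranks 25 and 22, β-catenin ranks 43 and 142), and chromosome 13, 94853202 to 94853454 (133 and 91 for Six2, 17 and 14 for β-catenin). The others were at chromosome 8, 91936033 to 91936284, chromosome 6, 21950157 to 21950429, chromosome 14, 59135250 to 59135796, chromosome 1, 167668935 to 167669436, chromosome 1, 92194328 to 92194580, chromosome 10, 123119791 to 123120150, and chromosome 4, 136773188 to 136773353. The last of these is the site ranked 1 and 3 for β-catenin. With ranks divided by list length, a choice made after seeing the data, the same 10 regions came first, led by the one on chromosome 13. Over the 122 regions that the shared sites merged into, the mean Six2 rank and the mean β-catenin rank were weakly correlated (Spearman's rho = 0.22, Pearson's r = 0.21, permutation p for rho = 0.0155, across regions).

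Six2 regions near the top of the Six2 lists were overlapped by β-catenin more often than those near the bottom. The share on reproducible β-catenin regions was 19.9% (15.8 to 24.6%) in the first quartile of the Six2 regions, 6.83% in the second, 6.23% in the third and 3.56% (1.85 to 6.14%) in the last. The odds differed 6.72-fold between the first and last quartile (Fisher's exact test, adjusted p = 3.32e-11 over 8 such comparisons). Counting any β-catenin peak, the share went from 49.6% to 11.3% (odds ratio 7.73, Fisher's exact test, adjusted p = 2.41e-27). With β-catenin replicate 1 alone the share went from 47.2% to 10.7% (Fisher's exact test, adjusted p = 6.17e-26), and with replicate 2 alone from 22.8% to 4.15% (Fisher's exact test, adjusted p = 9.58e-13). Across the β-catenin regions, the share on reproducible Six2 regions was 24.6% (17.7 to 32.7%) in the first quartile and 24.1% (17.2 to 32.1%) in the last (odds ratio 1.03, Fisher's exact test, adjusted p = 1.0). Counting any Six2 peak it was 55.1% and 42.3%, a difference that did not pass 0.05 (odds ratio 1.67, Fisher's exact test, adjusted p = 0.0539). On Six2 replicate 1 alone it was 54.3% in the first and 40.9% in the last quartile (odds ratio 1.72, Fisher's exact test, adjusted p = 0.0477), and on Six2 replicate 2 alone 25.4% and 24.8% (Fisher's exact test, adjusted p = 1.0). With ranks divided by list length, the shares in the outer quartiles were 17.8% and 4.15% for Six2 regions (odds ratio 5.00, Fisher's exact test, unadjusted p = 1.09e-08) and 23.2% and 24.1% for β-catenin regions (Fisher's exact test, unadjusted p = 0.888). The flat share holds for β-catenin regions found in both libraries. In the full lists, outside the chromosome 2 block, peaks on reproducible Six2 regions became fewer with rank. Replicate 1 had 103 on Six2 regions and 329 others in its first quartile, and 60 and 371 in its last. Replicate 2 had 48 and 254 in its first quartile, and 28 and 274 in its last. These falls were not tested.

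**Figure D3:**
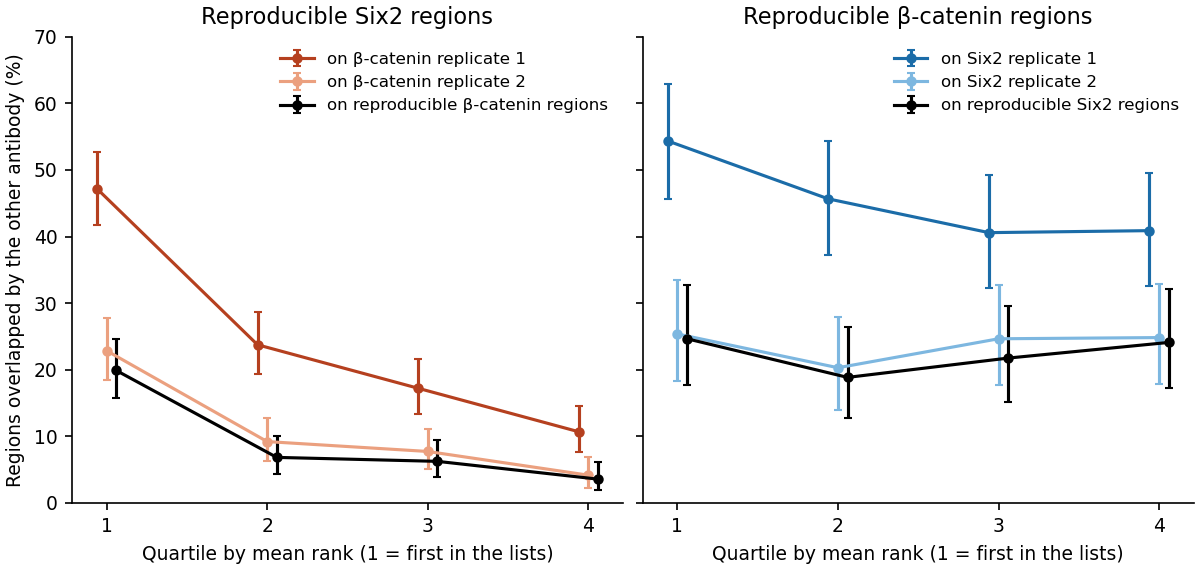
Share of reproducible regions (%) overlapped by the other antibody, by quartile of mean rank, with 95% exact intervals, for Six2 regions (left) and β-catenin regions (right). For Six2 regions the share on reproducible β-catenin regions (black) goes from 19.9% to 3.56%; for β-catenin regions the share on reproducible Six2 regions (black) is 24.6% and 24.1% in the outer quartiles.

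When each list was cut to its first 1208 peaks, libraries of the same antibody shared more sites than libraries of different antibodies. The Six2 libraries shared 51.7% (48.8 to 54.5%) and the β-catenin libraries 39.4% (36.6 to 42.2%). β-catenin replicate 1 overlapped Six2 replicate 1 in 19.2% and Six2 replicate 2 in 19.4% of its peaks, and β-catenin replicate 2 in 12.3% and 11.3%. All 4 values between antibodies lay above placement (permutation p = 0.001 each) and below both values within an antibody. The mean was 45.5% within and 15.5% between antibodies, a difference of 29.99 percentage points, and 15.8 points when the widest 1208 peaks were taken instead. The smallest p that the 3 ways of splitting the libraries allow is 0.333, so this difference has no test across libraries.

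**Figure D4:**
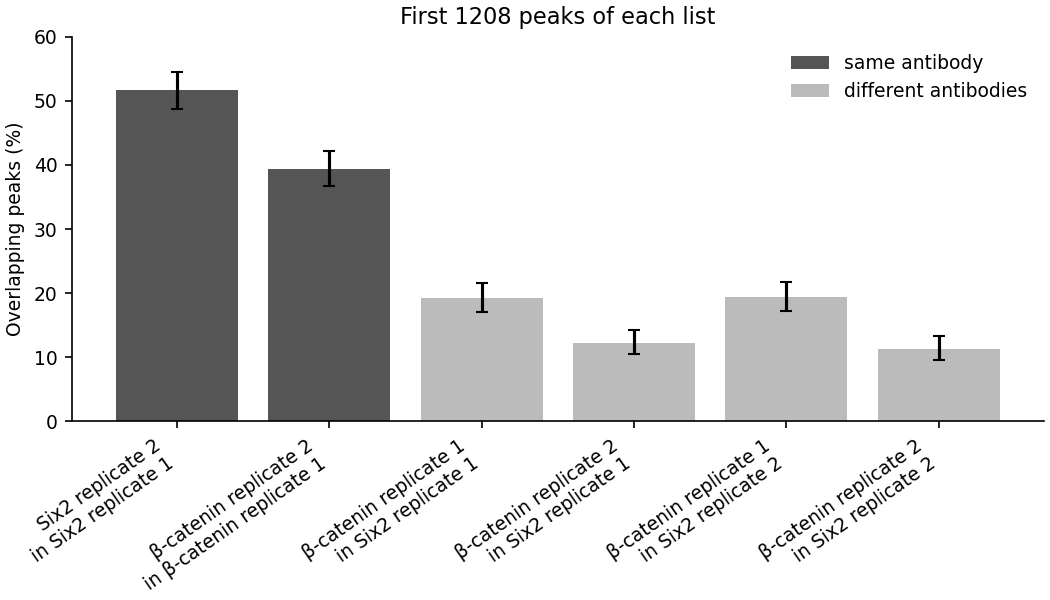
Share (%) of the first 1208 peaks of a list that overlap the first 1208 peaks of another, for the 6 pairs of libraries, with 95% exact intervals as error bars. The pairs of the same antibody (dark) stand at 51.7% and 39.4%, and the pairs of different antibodies (light) between 11.3% and 19.4%.

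The β-catenin libraries differed from each other in how often their peaks fell on Six2 sites. Among the first 1208 peaks, 255 of replicate 1 (21.1%, 18.8 to 23.5%) and 150 of replicate 2 (12.4%, 10.6 to 14.4%) lay on a reproducible Six2 region (odds ratio 1.89, Fisher's exact test over peaks, p = 1.27e-08). That cut keeps the whole replicate 2 list but only the leading part of replicate 1. At the first 500 peaks of every list, β-catenin replicates 1 and 2 overlapped Six2 replicate 1 in 14.6% and 11.4% of peaks. On Six2 replicate 2 the shares were 15.2% and 9.2%. These gaps were narrower than those between the same lists at 1208 peaks, and they were not tested. β-catenin regions seen in both libraries lay on reproducible Six2 regions in 22.3% of cases. Regions seen in replicate 1 only did so in 212 of 1320 cases (16.1%, or 18.1% without the chromosome 2 block), and regions seen in replicate 2 only in 28 of 657 (4.26%, 2.85 to 6.10%). Over the 5 Fisher's exact tests of this family, the share in both libraries was above that in replicate 2 only (odds ratio 6.46, adjusted p = 2.76e-21). Replicate 1 only was also above replicate 2 only (odds ratio 4.30, Fisher's exact test, adjusted p = 7.55e-16, and 4.95 without the block). The share in both libraries exceeded that in replicate 1 only by an odds ratio of 1.502 (Fisher's exact test, adjusted p = 0.00187), and of 1.30 without the block, which holds no Six2 peak (adjusted p = 0.0429). The tests of this family held neither rank nor width fixed. Peaks found in the other library had a median row of 394.0 in replicate 1 and 363.0 in replicate 2. Peaks not found had 1127.5 and 769.0. Regions in both libraries had a median width of 188 bp, against 140 bp for replicate 1 peaks. Recovery at like rank draws on the same peaks as these tests, with 122 peaks on Six2 regions found in each direction. It is not an independent difference. Outside the block, the share of replicate 1 peaks found in replicate 2 differed by 0.571 percentage points between peaks on Six2 regions and the others, weighted by rank quartile (95% interval -4.68 to 5.82). The share of replicate 2 peaks found in replicate 1, compared after seeing the data, was 35.4 points higher on Six2 regions (28.9 to 41.9). These Fisher tests count peaks and not libraries. The test on the first 1208 peaks also treats the lists as independent, though 476 of those replicate 2 peaks overlapped one of replicate 1.

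The peaks that coincided were close in position. Among the first 1208 peaks of the counted list with a partner midpoint within 500 bp, the median distance between midpoints was 34.0 bp between the Six2 libraries and 31.5 bp between the β-catenin libraries. Between antibodies it was 42.0 and 43.3 bp for β-catenin replicate 1 against Six2 replicates 1 and 2, and 46.0 and 57.3 bp for β-catenin replicate 2. The difference between these medians was not tested.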

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

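The lists without chromosome X, without the chromosome 2 block, by width, with any Six2 peak as partner, with scaled ranks and of equal length were tried only after the results were seen. The overlaps of the Six2 libraries (50.7 to 83.8% over 6 alternatives), of the β-catenin libraries (26.3 to 53.0% over 7) and of β-catenin with Six2 regions (9.12 to 47.2% over 12) were above random placement in every alternative run (permutation p = 0.001 each). The number of reproducible Six2 regions was 1348, and it was 879 with a reciprocal overlap of 50%, 655 with the first 50% of each list and 411 with the widest 50%. For β-catenin these numbers were 551, and 318, 320 and 166. The number of β-catenin regions on Six2 regions was 123, and 29, 52 and 17. As shares of the reproducible β-catenin regions these were 22.3%, and 9.12%, 16.25% and 10.2%. Part of the fall in numbers with shortened lists follows from the fewer peaks compared. The shares fell as well, and otherwise the cause was not tested. Dividing ranks by list length kept the same 10 named shared regions, 8 of the 10 named Six2 regions and all 10 named β-catenin regions. Leaving out 1 library, so that all peaks of the other stand for the antibody, gave 131 to 334 shared regions and shares from 12.4 to 45.4%. The overlaps within an antibody have no such alternative, since they need both libraries. Positions relative to genes, gene lists and motifs, and their variants, were not run, because no sequence or annotation of mm9 was used here. Depth is unknown, so a site missing from a list is not shown to be unbound.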

Other observations

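The tests on the chromosome 2 block, and that of β-catenin replicate 2 peaks at like rank, were chosen only after the results they bear on were seen, and the others here after the files were read but before their own results were. Of the 291 reproducible β-catenin regions with no Six2 peak on them, 42 (14.4%, 95% exact interval 10.6 to 19.0%) had a reproducible Six2 region within 50 kb. Random placement gave 5.18% on average and 8.93% at most over 1000 placements (permutation p = 0.001), so chance placement along chromosomes is argued against. Within 10 kb there were 12 such regions (4.12%, 2.15 to 7.09%), against 1.12% on average and 3.09% at most by placement. A shared preference for gene-rich stretches was not tested, because no annotation of mm9 was used here. Reproducible Six2 regions linked by gaps under 50 kb formed 2 groups of 4 regions, at chromosome 1, 170312157 to 170341028, and at chromosome 8, 91912771 to 91983592. Placement gave 0.029 groups on average and also reached 2 (permutation p = 0.003), so chance was not excluded by the bound set beforehand, which asked for more than the highest placement.

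β-catenin replicate 1 held a dense block of 146 peaks at chromosome 2, 146903063 to 147136350, a stretch of 233.3 kb. The block's peaks were wider than the rest of the list (median 357.5 against 136.0 bp, permutation p = 1e-05), covered 30.5% of the stretch, left no gap above 9143 bp and started at rank 441. The permutation treats neighbouring peaks of a block picked from these data as independent, so its p only describes this list. The next longest run of peaks in that library, with gaps of at most 20 kb, held 5. Binding of β-catenin called alike in both libraries is argued against, since replicate 2 had 0 peaks there where the ratio of list lengths gives 94.2. That ratio is too high a measure, since the median rank of the block's peaks was 1390. In decile 8 of replicate 1, which holds that rank, 13.4% of peaks were found in replicate 2. Depth is unknown, so binding below the threshold of replicate 2 is not excluded. Both Six2 libraries also had 0 peaks there, which does not bear on β-catenin. Extra DNA of a single contiguous segment in this library and broad binding in the cells of this library alone cannot be told apart: both would give wide peaks (357.5 bp), and the peaks cover too little of the stretch to meet the bound of 90% set for extra DNA. The matching input, which was not analysed here, would bear on it.

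The overlap of Six2 with β-catenin regions was far above placement, and a shared taste of both factors for the same stretches of 10 to 50 kb is argued against as its whole cause. After moving peaks by 10 to 50 kb, 0.542 β-catenin regions overlapped Six2 regions on average and 4 at most, against 123 observed. Places that give signal in any ChIP library, open chromatin included, would be expected to recur in every library. β-catenin replicate 1 peaks on Six2 regions were found in replicate 2 about as often as others of like rank, with a weighted difference of 0.571 percentage points (95% interval -4.68 to 5.82). The interval includes the 5 points set beforehand as the bound. In the other direction, 122 of 150 replicate 2 peaks on Six2 regions (81.3%) and 429 of 1058 others (40.5%) were found in replicate 1, a weighted difference of 35.4 points at like rank (95% interval 28.9 to 41.9), as recurring places would give. Both directions count the same overlaps, 122 of 334 replicate 1 peaks and 122 of 150 replicate 2 peaks on Six2 regions. They are therefore not independent, and replicate 1 had more peaks there, which lowers its share. Binding of both proteins at the same element would also give this recovery, so these explanations cannot be told apart here. The mock libraries, not analysed here, would bear on it, though their labels give no BIO culture. The dependence of the overlap on Six2 rank is open to the same 2 readings.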
